A study of Mus musculus with 6 samples.

How the data were processed

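PolyA-selected RNA of HT cells in culture was made into libraries with a TruSeq Stranded mRNA kit, per the labels' protocols, with 3 libraries of Mcrs1-transduced cells and 3 of vector control cells. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They give 1 Mcrs1ox group and do not say how many transduced lines it covers.

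The deposited gene table holds raw counts of reads for 43432 Ensembl genes in 6 libraries. Per the submitters' processing notes, the tools were fastp 0.22.0, HISAT2 2.2.1, featureCounts 2.0.1, R 4.2.1 and limma, with the GRCm38 build; the annotation release, the strand setting, the treatment of reads that match several genes and any filter are not given in the sources used here. A count for a gene that overlaps another, or that has near-identical copies, can therefore hold reads of its neighbour or copy. A second deposited table holds the authors' own comparison: log2 fold changes and mean log2 CPM, p-values with their adjusted p-values, and 2 score columns per the file headers, the moderated t and the B statistic of limma. It has 15901 rows for 15835 genes, and the 66 repeated rows were identical. All 6 count columns were matched to samples by name.

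Symbols and positions were taken from GENCODE M21, which is on the same GRCm38 build, and matched 42462 of the 43432 identifiers; the 970 without a symbol took 0.148% to 0.165% of counts. Genes were kept by edgeR's filterByExpr with the group, which left 12930, and library sizes were scaled by TMM. Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, as Mcrs1ox minus Control, and p-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. Common dispersion gave a biological coefficient of variation of 11.3%. At an unadjusted p under 0.05, 7497 genes passed. The median log2 fold change of all tested genes was -0.01.

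The 26 gene lists were fixed before the data were examined, as were the tests, the alternatives and the marker lists of 7 other cell types. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and set beside camera with an estimated correlation and fry. The estimated setting differs from the preset one in the correlation and also in its degrees of freedom. It uses the residual ones, few here, which by itself makes p larger. All 26 lists had at least 5 tested members. Genes are named by a fixed rule. It takes Mcrs1, then the 6 annotated genes with the largest increase and the 6 with the largest decrease among those past 0.05 with a mean of at least 3 log2 CPM and separated groups. It adds up to 4 members with the smallest adjusted p in the direction of each list that passed camera, and up to 3 members of the 3 lists that did not pass but had the largest share of changed members (collagens, the ATF4 response and chemokines). H2-K1, H2-D1, B2m, Tap1, Nlrc5, Psmb8 and Cd274 are given in every case. A gene that the rule takes from the mesenchymal list is not reported here. Other list members named, mostly those that went against their list or that make up a small count, and the changed cell type markers were chosen after their values were seen.

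A gene with 0 counts in a group is given a bound on its fold change, against a floor of 3 counts over the group, and one with 1 to 3 counts the ratio of counts per library size with a 95% exact interval. These intervals and bounds cover counting error only. Intervals given for medians over genes are 95% bootstrap intervals from 10000 resamplings of the genes. They treat genes as independent and do not cover the spread between libraries. A bound also falls when a library of the group at 0 is left out, as the floor stays at 3 counts. Library totals ran from 18040846 to 25569855 counts, and the 10 most abundant genes took 7.27% to 7.98% of each library. No pair of libraries was a duplicate: within a group the lowest chi-square per degree of freedom was 7.10.

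The procedure was tested on simulated data with 12481 genes passing the filter, of which 200 were changed. At this depth 30 of 67 genes changed 1.5-fold were recovered (44.8%), 59 of 67 changed 2-fold (88.1%) and 65 of 66 changed 4-fold (98.5%), and 14 of 168 calls were false (8.33%). Far fewer genes changed there than the 6792 called in the data, and adjustment is stricter when fewer genes change. These shares therefore do not give the sensitivity of the real comparison. A list raised 1.5-fold had an adjusted p of 2.95e-50 and 0 other lists were called. Simulated genes varied independently and no other list was changed. This cannot show how often the list test errs when genes of a list are correlated. Alternatives were DESeq2's size factors, library size alone, no filter and a stricter filter (CPM of at least 1 in 3 libraries), limma-voom, the DESeq2 1.42.0 Wald test, a threshold of 0.01, the replicate number as a block, and each library left out.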

Results

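Messenger RNA was profiled in HT, a mouse pancreatic cancer cell line, after transduction with a lentivirus carrying mouse Mcrs1 (Mcrs1ox) or with the vector alone (Control). Each group had 3 libraries, made from polyA-selected RNA of cells in culture. Library totals were 20328606, 19051433 and 18040846 counts in Control and 19188956, 21056953 and 25569855 in Mcrs1ox. At least 1 count was recorded for 20757 of the 43432 genes listed, and 12930 genes had enough counts to be tested. Levels below are TMM-normalized CPM (counts scaled to a common library size), as mean ± SD of n = 3 libraries, and log2 fold changes are Mcrs1ox minus Control ± SE.

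The comparison of Mcrs1ox with vector control asked which genes Mcrs1 regulates in these cells. Mcrs1, a member of the NSL and INO80 chromatin complexes, was higher in Mcrs1ox, at 133 ± 10.9 CPM against 88.1 ± 3.78 CPM in Control. Its log2 fold change was 0.60 ± 0.081, or 1.51-fold, with an adjusted p of 9.47e-05. Counts of Mcrs1 were 1788, 1766 and 1537 in the Control libraries and 2442, 2963 and 3294 in the Mcrs1ox libraries. The gene (ENSMUSG00000037570) lies on the minus strand of chromosome 15 at 99242817 to 99251961 (GRCm38) and overlaps Kcnh3 and 1700120C14Rik on the other strand. The strand setting of the counting and whether reads of the lentiviral copy fall in this count are not given in the sources used here.

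Beside that difference in Mcrs1, much of the transcriptome differed. At an adjusted p under 0.05, 6792 genes changed (52.5% of those tested), of which 3426 were higher and 3366 lower in Mcrs1ox. A change of at least 2-fold was found for 2164 genes, 1310 higher and 854 lower. At least 32-fold changes were found for 108 genes higher and 134 lower. In 7819 genes (60.5%) every Mcrs1ox library lay on the same side of every Control library, where chance gives 10%. Correlations of log2 CPM across genes were 0.988 to 0.992 within groups and 0.891 to 0.910 between groups, and the first principal component, which held 87.9% of the variance, separated the groups.

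Among the genes with the largest increases were several that encode products of mucosal epithelia. Tff3, a secreted trefoil peptide, had 2 counts over the Control group and 4673 over the Mcrs1ox group, a ratio of 2063 with a counting interval (95%) of 570.7 to 17040. Dmbt1, a secreted mucosal glycoprotein, rose from 2.59 ± 0.188 to 680 ± 324 CPM (log2 fold change 8.04 ± 0.41, adjusted p 1.01e-06). Cftr, the epithelial chloride channel, had 3 counts in Control and 1108 in Mcrs1ox, a ratio of 326.1 (111.3 to 1584). The proton channel gene Otop3 rose to 82.9 ± 17.6 CPM from 7 Control counts, all in replicate 1 (9.35 ± 0.42, adjusted p 1.05e-07); without that library Control had 0 counts and Otop3 was at least 1058-fold higher. Neighbouring genes of a pair of mast cell proteases on chromosome 14 were also in this group: Mcpt2 rose by 9.24 ± 0.78 on the log2 scale (adjusted p 3.35e-05), and Mcpt4, with 0 counts in Control and 1923 in Mcrs1ox, was at least 566-fold higher (adjusted p 9.59e-05). Mcrs1ox replicate 3 had the highest counts of these proteases, with 4474 of Mcpt2 and 1228 of Mcpt4, against 1185 and 1190 of Mcpt2 and 324 and 371 of Mcpt4 in replicates 1 and 2. The counts of Tff3 and Dmbt1 were likewise highest in that library, at 2811 and 27166, against 956 and 906 for Tff3 and 10063 and 9478 for Dmbt1. Without it the log2 fold change of Mcpt2 was 8.54, Mcpt4 was at least 338-fold higher and the Tff3 ratio was 1357 (375.2 to 11220). Leaving out Control replicate 1, which held both Control counts of Tff3, gave bounds of at least 891-fold for Tff3 and at least 367-fold for Mcpt4, and a Cftr ratio of 211.3 (72.13 to 1026), while without Control replicate 3 the Cftr ratio was 669.6 (119.9 to 26470). Control counts of Mcpt4 and Cftr did not change without Control replicate 1, so those moves follow from the lower depth alone.

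The largest decreases were near-complete losses of genes with ample counts in Control. Igfbp7, a secreted insulin-like growth factor binding protein, went from 155 ± 6.40 CPM in Control to 1 count over the Mcrs1ox group, against 8963 in Control (Control to Mcrs1ox ratio 10150, interval 1822 to 401000). Atp11a, a phospholipid flippase on chromosome 8, had 2571 counts in Control and 0 in Mcrs1ox and was at least 971-fold lower. Tcaf1, a regulator of TRP channels, and Wls, a carrier of secreted Wnt proteins, had 2028 and 1457 counts in Control and 0 in Mcrs1ox, so they were at least 766-fold and at least 550.1-fold lower. Prdx4, a peroxiredoxin of the endoplasmic reticulum, had 3514 counts against 2 (ratio 1990, interval 550.5 to 16440), and Gyg, the primer of glycogen synthesis, had 1286 against 1 (ratio 1457, interval 261 to 57580). The largest adjusted p among these 6 genes was 2.36e-08. Leaving out a library moved these sizes through the few Mcrs1ox counts and through the depth. Without Mcrs1ox replicate 2, which held all Mcrs1ox counts of Igfbp7, Prdx4 and Gyg, those genes were at least 2333-fold, at least 915-fold and at least 335-fold lower. Without Mcrs1ox replicate 3 the ratios were 6148 (1103 to 242900), 1205 (333.4 to 9956) and 882.1 (158 to 34870), and the bounds 588-fold for Atp11a, 464-fold for Tcaf1 and 333-fold for Wls. The Mcrs1ox counts of these genes did not change without replicate 3, so those moves follow from the lower depth alone.

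Genes of MHC class I antigen processing and presentation, the pathway that displays peptides to CD8 T cells, were mostly higher in Mcrs1ox. Of 15 tested members 13 rose, 2 fell and 0 did not pass, with a median log2 fold change of 0.45. Adjusted over the list alone the counts were also 13 and 2. The heavy chain genes H2-K1 and H2-D1 rose by 1.10 ± 0.099 (243 ± 31.9 to 522 ± 37.0 CPM, adjusted p 4.37e-06) and 0.92 ± 0.12 (369 ± 60.2 to 698 ± 66.8 CPM, adjusted p 6.22e-05). They lie on chromosome 17 at 33996017 to 34000347 and 35262730 to 35267499 (GRCm38), are near-identical to other class I genes, and how the counting split shared reads is not given in the sources used here. The peptide transporter subunits rose from low levels, Tap1 by 2.49 ± 0.35 to 3.22 ± 0.596 CPM and Tap2 by 1.86 ± 0.23 to 5.63 ± 0.701 CPM (adjusted p 0.000124 and 4.46e-05). Tapbp (tapasin), which loads peptides onto the heavy chains, rose by 1.19 ± 0.095 (adjusted p 1.79e-06). The members that fell were B2m, the shared light chain, and Nlrc5, a transactivator of class I genes. B2m went from 172 ± 4.54 to 146 ± 9.46 CPM (-0.23 ± 0.073, adjusted p 0.0197), and lost its call without Control replicate 2 (0.0785), Control replicate 3 (0.0657) or Mcrs1ox replicate 2 (0.0693). Nlrc5 fell by 3.40 ± 0.58 on the log2 scale, from 59 counts to 6 (adjusted p 0.000507), and without Mcrs1ox replicate 2 it had 2 counts there and a Control to Mcrs1ox ratio of 23.04 (6.102 to 194.7). Psmb8, a subunit of the immunoproteasome, had counts of 0, 1 and 1 in Control and 0, 4 and 1 in Mcrs1ox, too few to test. The list ranked above the other genes (camera adjusted p 0.0142; adjusted p = 0.32 with an estimated correlation).

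**Figure D1:**
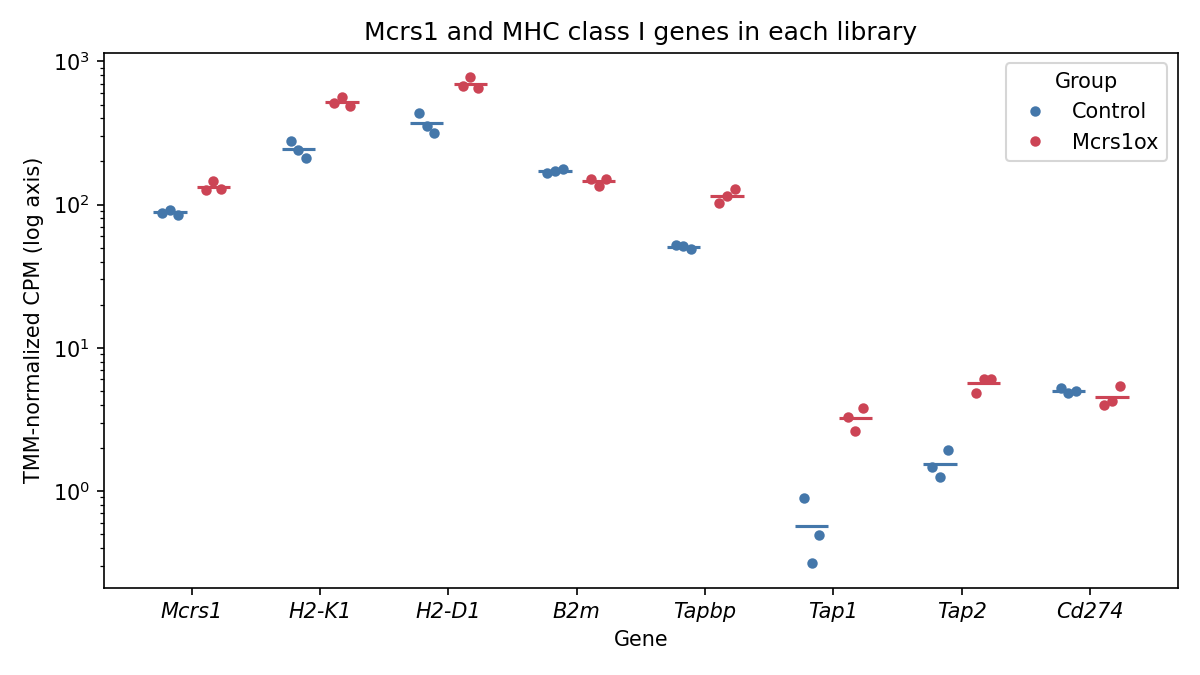
Levels of Mcrs1, MHC class I genes and Cd274 in each library, in TMM-normalized CPM on a log axis; points are the 3 libraries of each group and bars are group means. H2-K1 was 243 CPM in Control and 522 CPM in Mcrs1ox, B2m 172 and 146 CPM, and Cd274 5.02 and 4.55 CPM.

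Interferon-related genes formed the next group of immune genes that were higher. In the type I interferon response list, 26 of 33 tested members rose, 2 fell and 5 did not pass, with a median of 1.08, and the counts adjusted over the list alone were the same. Lgals3bp rose by 2.37 ± 0.088 (167 ± 3.15 to 861 ± 89.3 CPM), Ifitm3 by 3.42 ± 0.18, the transcription factor Irf7 by 4.29 ± 0.34 and the antiviral enzyme Oas2 by 6.07 ± 0.63, with 1.59e-05 as the largest adjusted p of these. Oas2 had 4 counts in Control and 343 in Mcrs1ox, and without Control replicate 2 it had 1 and 343, a ratio of 202.1 (36.03 to 8005). The members that fell were Ifit2 (-1.36 ± 0.28) and Herc6 (-1.22 ± 0.27). The list passed camera (adjusted p 8.52e-07; adjusted p = 0.408 with an estimated correlation). Of the interferon-gamma inducible GTPases and regulators, 12 of 15 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.80. Examples were the receptor chain Ifngr2 (1.39 ± 0.083), the adhesion molecule Icam1 (0.90 ± 0.098) and the guanylate-binding proteins Gbp9 (3.21 ± 0.33) and Gbp8 (4.32 ± 0.50), which overlap each other and Gbp4 on the same strand. Gbp8 had 7 counts in Control and 168 in Mcrs1ox, and without Control replicate 2 it had 2 and 168, a ratio of 49.49 (13.49 to 412). For this list the camera adjusted p was 0.00218 (adjusted p = 0.408 with an estimated correlation).

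The other immune lists did not pass camera, though each had members that changed. Of the non-classical MHC class I genes, 5 of 8 rose (H2-T22, H2-T23, H2-T10, H2-Q4 and Mr1) and 0 fell, with a median of 0.68 (5 and 0 adjusted over the list alone; camera adjusted p 0.139; adjusted p = 0.408 with an estimated correlation). MHC class II had H2-DMa and Rfxank higher among 6 tested genes and 0 lower, where Rfxank did not pass without Control replicates 2 (0.091) or 3 (0.07) or Mcrs1ox replicates 2 (0.0616) or 3 (0.0611) (2 and 0 adjusted over the list alone; camera adjusted p 0.822; adjusted p = 0.868 with an estimated correlation). Of 17 ligands and checkpoints of T cells and NK cells, 7 rose and 3 (Pvr, Raet1d and Lgals1) fell (7 and 3 adjusted over the list alone; camera adjusted p 0.366; adjusted p = 0.525 with an estimated correlation). Cd274, which encodes PD-L1, was at 5.02 ± 0.239 CPM in Control and 4.55 ± 0.769 CPM in Mcrs1ox, a difference of -0.13 ± 0.19 that did not pass (adjusted p 0.569). Chemokines and cytokines split into 9 higher and 8 lower of 24 (9 and 8 adjusted over the list alone; camera adjusted p 0.309; adjusted p = 0.606 with an estimated correlation). The T cell and monocyte chemokine Cx3cl1 rose by 1.68 ± 0.081, the neutrophil chemokine Cxcl5 by 3.47 ± 0.23, and the alarmin Il33 by 5.37 ± 0.24, from 4.40 ± 1.19 to 182 ± 45.6 CPM. NF-kB targets had 7 higher and 6 lower of 19 (7 and 7 adjusted over the list alone; camera adjusted p 0.775; adjusted p = 0.868 with an estimated correlation).

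Epithelial genes were higher and mesenchymal genes lower in Mcrs1ox. Of 23 tested epithelial and ductal genes 19 rose and 2 fell (19 and 3 adjusted over the list alone), with a median of 1.47. The mucin gene Muc1 rose by 2.54 ± 0.073 (107 ± 4.09 to 621 ± 22.5 CPM), the ductal keratin Krt19 by 2.75 ± 0.12 (806 ± 60.6 to 5407 ± 815 CPM), Krt20 by 2.31 ± 0.11 and Lcn2, a secreted siderophore-binding protein, by 5.23 ± 0.20, with 3.98e-08 as the largest adjusted p. The tight junction gene Cldn4 (-3.83 ± 0.57) and the keratin Krt18 (-0.29 ± 0.092) fell. Without Mcrs1ox replicate 3 Cldn4 had 67 counts in Control and 1 in Mcrs1ox, a ratio of 45.96 (7.971 to 1842). Krt18 did not pass without Control replicates 2 (0.104) or 3 (0.0675) or Mcrs1ox replicates 1 (0.123) or 3 (0.0515). The list had a camera adjusted p of 1.74e-18 (adjusted p = 0.105 with an estimated correlation). Of 20 mesenchymal genes 15 fell and 1, Loxl2 (0.26 ± 0.087), rose (16 and 1 adjusted over the list alone), with a median of -1.10. Loxl2 did not pass without Control replicates 2 (0.0704) or 3 (0.0794) or Mcrs1ox replicates 2 (0.0541) or 3 (0.061). The matrix protein gene Thbs1 (-4.55 ± 0.20) and the N-cadherin gene Cdh2 (-1.33 ± 0.094) fell, while tenascin C (Tnc) had 309 counts in Control and 2 in Mcrs1ox, a ratio of 175 (interval 48.04 to 1451). Cdh2 lies on chromosome 18, whose 330 tested genes had a median log2 fold change of -0.43. The mesenchymal list had a camera adjusted p of 1.24e-07 (adjusted p = 0.0906 with an estimated correlation). Markers of fibroblasts summed to 3.59 ± 0.042 CPM in Control and 2.07 ± 0.381 CPM in Mcrs1ox, and those of pancreatic acinar cells to 40.3 ± 1.93 and 17 ± 1.41 CPM.

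Targets of YAP/TEAD and of MAPK signalling were lower. Of 17 YAP/TEAD targets 12 fell and 2, Nt5e (1.39 ± 0.11) and Wwc1 (0.90 ± 0.068), rose (12 and 2 adjusted over the list alone), with a median of -1.03. The matricellular gene Ccn1 went from 827 ± 62.4 to 106 ± 7.03 CPM (-2.97 ± 0.089, adjusted p 1.99e-09), and Ankrd1 (-2.49 ± 0.076), Amotl2 (-1.74 ± 0.071) and Arhgef17 (-6.14 ± 0.22) fell as well. The list's camera adjusted p was 2.09e-09 (adjusted p = 0.0604 with an estimated correlation). Of 25 genes of MAPK output 17 fell and 1, Fos (0.93 ± 0.22), rose (17 and 1 adjusted over the list alone), with a median of -0.57. The phosphatase gene Dusp5 (-2.13 ± 0.081), the transcription factor genes Egr1 (-3.49 ± 0.14) and Fosl1 (-1.41 ± 0.087) and the EGFR ligand Hbegf (-1.53 ± 0.075) fell, with 2.34e-07 as the largest adjusted p. Egr1 and Hbegf also lie on chromosome 18. The MAPK list had a camera adjusted p of 6.22e-07 (adjusted p = 0.0899 with an estimated correlation).

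Genes of ribosome biogenesis and the partners of Mcrs1 in the NSL complex were mostly lower, and 18 of 36 proliferation genes fell. In the list of ribosome biogenesis and Myc targets 22 of 30 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.50. Mybbp1a (-0.85 ± 0.076, 1009 ± 33.4 to 559 ± 29.5 CPM), Ddx21 (-0.83 ± 0.070), Nolc1 (-0.81 ± 0.071) and Odc1 (-0.73 ± 0.070), the first enzyme of polyamine synthesis, fell (camera adjusted p 1.28e-05 for the list; adjusted p = 0.287 with an estimated correlation). Of 36 proliferation genes 18 fell, 1 (Mcm3, 0.34 ± 0.12) rose and 17 did not pass (18 and 1 adjusted over the list alone). The mitotic genes Cdc20 (-1.09 ± 0.099), Kif20a (-1.11 ± 0.10), Ube2c (-0.78 ± 0.11) and Aurka (-0.76 ± 0.12) were among those that fell, and Kif20a is on chromosome 18. The proliferation list had a camera adjusted p of 0.0182 (adjusted p = 0.606 with an estimated correlation) and did not pass without Mcrs1ox replicate 3 (0.1). Mcm3 passed without Mcrs1ox replicate 3 and in no other left-out fit (0.0508, 0.116 and 0.102 without Control replicates 1, 2 and 3, and 0.129 and 0.114 without Mcrs1ox replicates 1 and 2). Of the 8 NSL complex partners 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.37. The chromatin cofactor Hcfc1 (-0.68 ± 0.074), Kansl2 (-0.50 ± 0.075), Wdr5 (-0.46 ± 0.080) and Kansl3 (-0.36 ± 0.076) fell. Its camera adjusted p was 0.0399 (adjusted p = 0.421 with an estimated correlation), and 0.058, 0.0559 and 0.0717 without Control replicate 2, Control replicate 3 and Mcrs1ox replicate 3. The INO80 complex had 5 of 14 genes lower (Ino80c, Ino80e, Ruvbl1, Ruvbl2 and Actl6a) and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p 0.271; adjusted p = 0.421 with an estimated correlation). Ino80e did not pass without Control replicate 2 (0.0597) or Mcrs1ox replicate 1 (0.0566).

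NRF2 targets and genes of fatty acid synthesis were mostly higher in Mcrs1ox, and 18 of 34 genes of hypoxia and glycolysis rose. Of 24 NRF2 targets 16 rose and 2, Hmox1 (-1.48 ± 0.089) and Txnrd1 (-0.72 ± 0.078), fell (16 and 2 adjusted over the list alone), with a median of 0.42. The glutathione genes Gstm1 (1.73 ± 0.069), Gsta4 (2.33 ± 0.12) and Gclc (2.48 ± 0.11, 25.9 ± 1.94 to 145 ± 20.1 CPM) rose, as did the carbonyl reductase Cbr3 (4.32 ± 0.34). The NRF2 list had a camera adjusted p of 0.00107 (adjusted p = 0.304 with an estimated correlation). In fatty acid synthesis 9 of 14 rose, including the transcription factor Srebf1 (1.13 ± 0.072), Acss2 (1.54 ± 0.14), Acsl3 (1.05 ± 0.12) and the desaturase Scd2 (0.47 ± 0.078). The 3 that fell were the fatty acid synthase Fasn, Acly, which makes its acetyl-CoA, and the desaturase Fads1 (-0.36, -0.22 and -0.28), and Acly did not pass without Control replicates 2 (0.15) or 3 (0.106) or Mcrs1ox replicates 1 (0.107) or 2 (0.0561). Counts for this list were 9 and 3 adjusted over the list alone, and its camera adjusted p was 0.0399 (adjusted p = 0.408 with an estimated correlation), with 0.0718 without Control replicate 1 and 0.0565 without Mcrs1ox replicate 3. In hypoxia and glycolysis 18 rose, 5 fell and 11 did not pass (21 and 5 adjusted over the list alone). The glycolytic enzymes Pfkl (1.5 ± 0.12), Aldoc (2.86 ± 0.27), Gpi1 (0.72 ± 0.083) and Hk1 (0.58 ± 0.069) rose, while those lower were Car12, Hk2, Pfkfb3, Eno2 and the oxygen sensor Egln3, which had 481 counts in Control and 0 in Mcrs1ox (at least 182-fold lower, and at least 110.0-fold without Mcrs1ox replicate 3). Eno2 did not pass without Control replicate 3 (0.106) or Mcrs1ox replicates 1 (0.0901) or 3 (0.077), nor Pfkfb3 without Mcrs1ox replicate 1 (0.0519). This list had a camera adjusted p of 0.0399 (adjusted p = 0.628 with an estimated correlation), and 0.0502 without Control replicate 1 and 0.0565 without Mcrs1ox replicate 3. Cholesterol biosynthesis had 7 higher and 9 lower of 25 (8 and 9 adjusted over the list alone; camera adjusted p 0.608; adjusted p = 0.868 with an estimated correlation).

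Transcripts of the mitochondrial genome were lower in Mcrs1ox, where 10 of 12 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -1.14. The complex I genes mt-Nd1 (-1.89 ± 0.20, 3392 ± 342 to 918 ± 284 CPM), mt-Nd4 (-1.35 ± 0.18) and mt-Nd5 (-1.13 ± 0.16) and the complex IV gene mt-Co3 (-1.22 ± 0.15) were examples. The camera adjusted p was 0.00193 (adjusted p = 0.421 with an estimated correlation). Mitochondrially encoded genes took 1.63%, 1.76% and 2.09% of counts in the Control libraries and 1.13%, 0.827% and 1.37% in the Mcrs1ox libraries, a share that can also move with RNA quality. Nuclear-encoded genes of oxidative phosphorylation had 16 higher and 3 lower (Cox6c, Atp5a1 and Cox5a) of 35 (16 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p 0.249; adjusted p = 0.731 with an estimated correlation).

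The remaining stress and matrix lists did not pass camera. Collagens had 4 of 12 higher and 5 lower (4 and 5 adjusted over the list alone): the basement membrane genes Col4a1, Col4a2 (0.39 ± 0.071), Col4a5 (1.03 ± 0.13) and Col18a1 rose, and Col5a1 (-2.56 ± 0.11), Col1a1, Col6a3, Col7a1 and Col8a1 fell. Col4a1 did not pass without Control replicate 2 (0.0926), and Col6a3 passed without Mcrs1ox replicate 1 and in no other left-out fit (0.0882, 0.0956 and 0.0583 without Control replicates 1, 2 and 3, and 0.0833 and 0.124 without Mcrs1ox replicates 2 and 3). Their camera adjusted p was 0.391 (adjusted p = 0.606 with an estimated correlation). Of 33 genes of the ATF4 and amino acid response 19 fell and 5 rose (19 and 5 adjusted over the list alone; camera adjusted p 0.0575; adjusted p = 0.59 with an estimated correlation). The secreted glycoprotein gene Stc2 (2.37 ± 0.080) and the arginine transporter Slc7a3 (2.11 ± 0.11) rose together with Aldh1l2, Nupr1 and Pck2, while the lipoprotein receptor Vldlr (-3.83 ± 0.21), the serine synthesis enzyme Phgdh (-1.07 ± 0.089) and the asparagine synthetase Asns (-0.75 ± 0.073) were among those that fell. The ATF4 list passed camera, in the same direction, without Control replicate 3 (0.0263) or Mcrs1ox replicate 2 (0.0285). Targets of p53 had 9 lower and 2 (Btg2 and Perp) higher of 20 (10 and 3 adjusted over the list alone; camera adjusted p 0.209; adjusted p = 0.408 with an estimated correlation). Chaperones of the unfolded protein response had 8 higher and 4 (Hyou1, Manf, Dnajb9 and Dnajb11) lower of 17 (8 and 5 adjusted over the list alone; camera adjusted p 0.495; adjusted p = 0.606 with an estimated correlation). Each of those 4 lost its call in some left-out fits: Hyou1 without Control replicate 2 (0.0535) or Mcrs1ox replicate 1 (0.0543), Manf without Control replicate 1 (0.0695) or Mcrs1ox replicates 1 (0.0572) or 3 (0.0662), and Dnajb9 without Control replicates 2 (0.0606) or 3 (0.0982) or Mcrs1ox replicate 2 (0.0807). Dnajb11 did so without Control replicates 1 (0.138) or 2 (0.11) or Mcrs1ox replicates 1 (0.157) or 3 (0.133).

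Of the 26 lists, 14 passed camera, 7 higher and 7 lower. With an estimated correlation 0 lists passed after adjustment and 4 did at an unadjusted p under 0.05 (YAP/TEAD targets, MAPK output, mesenchymal, and epithelial and ductal genes). By fry, which asks whether the genes of a list move on balance one way and does not set them against other genes, 23 lists passed.

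**Figure D2:**
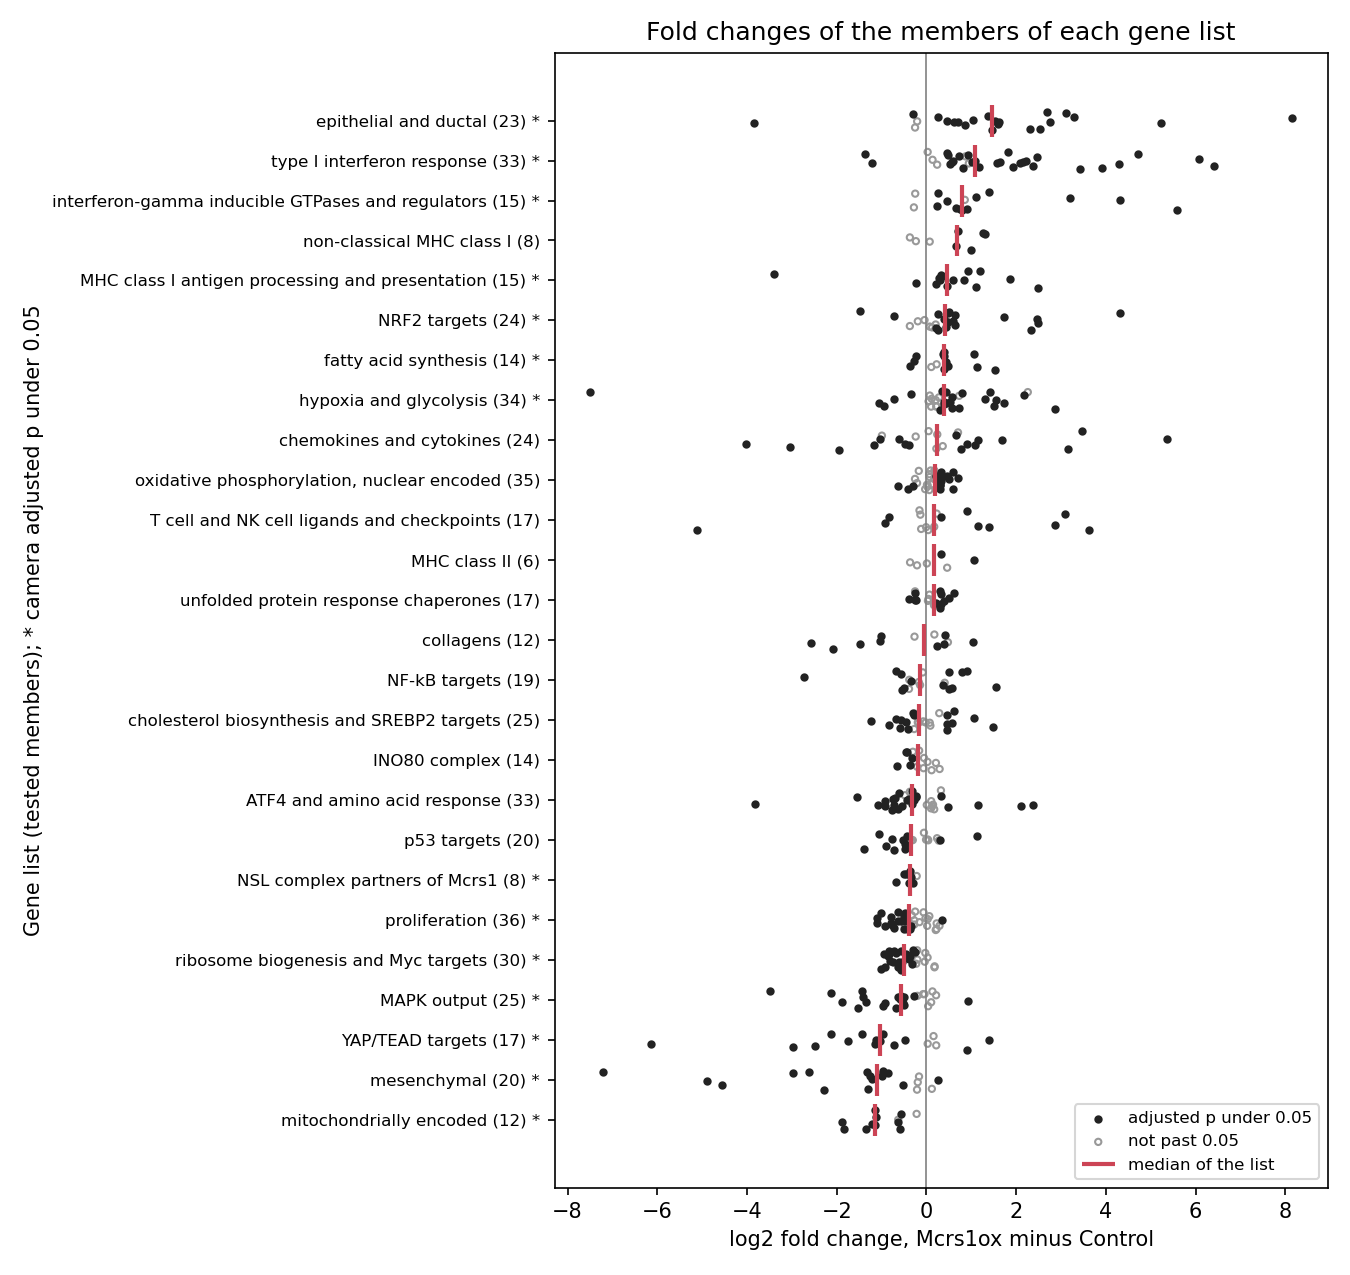
Log2 fold changes (Mcrs1ox minus Control) of the tested members of the 26 gene lists; filled points passed an adjusted p of 0.05, open points did not, red bars are list medians, and genes with 0 counts in a group stand at their bound. Medians ran from -1.14 for mitochondrially encoded genes to 1.47 for epithelial and ductal genes, and the 14 lists with an asterisk passed camera.

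Markers of each other cell type summed to a group mean of 40.3 CPM or less, the highest being acinar markers in Control. T cell and NK cell markers summed to 18.4 ± 1.56 CPM in Control and 19.5 ± 2.23 CPM in Mcrs1ox, with 0 of 2 tested genes changed. B cell markers summed to 0.204 ± 0.125 and 0.470 ± 0.226 CPM and endocrine markers to 0.121 ± 0.024 and 0.052 ± 0.090 CPM, with 0 tested genes in either. Myeloid markers summed to 15.0 ± 3.20 and 20.1 ± 3.05 CPM, with Cd68 higher, and endothelial markers to 3.57 ± 0.558 and 4.88 ± 0.866 CPM, with Cdh5 higher. Of the fibroblast and acinar markers, whose sums stand with the mesenchymal and ductal genes, Col1a1 was lower among 2 tested fibroblast genes, and both tested acinar genes, the elastase Cela1 and the trypsinogen Try5, were lower.

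The authors' deposited table of the same comparison, made with limma, listed 15835 genes, of which 12838 were also tested here. It called 7054 genes, 3236 higher and 3818 lower, and 2433 of them by at least 2-fold. Of the 6792 genes called here, 6312 (92.9%) were also called in the authors' deposited table in the same direction and 0 in the opposite one, and across the shared genes, which are not independent replicates, log2 fold changes correlated with r = 0.997. For Mcrs1 the authors' deposited table gave a log2 fold change of 0.60 with an adjusted p of 6.74e-05.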

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

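Alternatives to the normalization, filter, test and libraries left Mcrs1 higher and its call in place, and 0 genes changed in the opposite direction under any of them. Genes changed numbered 6787 with DESeq2's size factors, 6767 with library size alone, 7350 without a filter, 6487 with the stricter filter, 6782 with limma-voom, 6690 with DESeq2 and 5112 at a threshold of 0.01. Leaving out a library gave 5733 to 6573 genes changed (2972 to 3388 higher, 2761 to 3235 lower), 2198 to 2303 by at least 2-fold, 5498 to 6015 shared with the authors' deposited table, 10 to 15 lists, a log2 fold change of 0.53 to 0.65 for Mcrs1 and an adjusted p of 0.00777 to 0.022 for the MHC class I list. The number of lists depended on the list test: camera with an estimated correlation called 0 in place of 14 and fry 23, and the MHC class I list had an adjusted p of 0.32 with an estimated correlation. Fry does not compare a list with other genes. Lists with an estimate near the preset value, such as YAP/TEAD targets (-0.004) and MAPK output (0.015), lost their calls too. For YAP/TEAD targets the estimate lay below the preset value of 0.01, yet the camera p went from 1.61e-10 to 0.00232. A larger correlation is thus argued against as the cause for that list. With an estimated correlation, camera also uses the few residual degrees of freedom of these libraries, which by itself makes p larger. A call lost in this way does not by itself show that the genes of a list are correlated. How much each part contributed was not tested. The MHC class II list, never past the threshold, reversed to lower without Control replicate 3 (adjusted p 1, and 0.739 to 1 over the left-out libraries); the cause was not tested. The ATF4 list passed with library size alone (0.0405), without a filter (0.018) and with limma-voom (0.0173), as did oxidative phosphorylation with limma-voom (0.0409), and hypoxia and glycolysis did not pass under the stricter filter (0.05). Of the genes named by the fixed rule, B2m lost its call without 3 of the libraries in turn and lay above the threshold of 0.01 (0.0197), and Nlrc5 was not tested under the stricter filter. Among other genes named, Col6a3 and Col8a1 were not tested there, and Mcm3 did not pass with limma-voom (0.0597), Col6a3 with DESeq2 (0.0874) and Dnajb11 without a filter (0.0593). Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.077, 0.089 and 0.248, and not every sample correlated best with its own number. With the replicate block 7160 genes and 12 lists changed, the MHC class I list had 0.0141 and Mcrs1 0.60, and the NSL (0.0626) and fatty acid (0.0505) lists did not pass. DESeq2 gives no value for the list tests. Psmb8 had too few counts to test. The simulation, run at 1 depth with 3 libraries per group and only 200 changed genes, recovered 44.8% of 1.5-fold changes.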

Other observations

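The tests of mast cells, of copy number on chromosomes 17 and 18, of genes shuffled over chromosomes and of reads shared among heavy chain genes were chosen after the results were seen. The question of a separate subline was also raised then and was not tested.

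Genes of the intestinal and gastric epithelium were higher in Mcrs1ox. After Tff3, Dmbt1 and Cftr had been seen to rise, a list of 40 other such genes was written without sight of their values, and 23 could be tested. Of these 21 rose and 1 (Slc44a3, -1.63 ± 0.23) fell, also when adjusted over the list alone, with a median log2 fold change of 3.22. The others were not tested, so only part of the list is described. Some members could be tested mainly through their Mcrs1ox counts, such as Prap1 (2 in Control, 266 in Mcrs1ox) and Phgr1 (4 and 434). That tilts the list toward higher, and with it the median and the camera test, which include these members. Mep1a, the member at the median, had 13 counts in Control and 141 in Mcrs1ox. Tm4sf4, Tspan8 and Lgals2, the tested members with most Control counts, rose by 0.52, 1.05 and 1.68 on the log2 scale. The brush border cadherins Cdhr5 and Cdhr2 rose by 4.78 ± 0.16 and 2.48 ± 0.13, the mucin glycosyltransferase Gcnt3 by 2.73 ± 0.11, the junction protein Tjp3 by 4.37 ± 0.17 and the gastric secreted protein Gkn2 by 4.08 ± 0.27. Camera gave p = 9.7e-18 for the list and p = 0.0576 with an estimated correlation, so a hypothesis that the Mcrs1ox cells may carry more of such an epithelial programme met its test by camera and missed the threshold under the estimated correlation. The number of these genes that pancreatic ductal cells also express was not counted.

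The 108 genes at least 32-fold higher and 134 at least 32-fold lower stand beside a 1.51-fold difference in Mcrs1. Deletion of chromosome blocks, as the whole cause of the losses, is argued against by the 255 nearest tested neighbours of the lower genes. Their median log2 fold change was -0.0751 (interval -0.172 to 0.0129), with neighbours that were themselves at least 32-fold lower left out. Lower genes formed 5 adjacent pairs, against a mean of 1.37 and a 95th percentile of 4 in random draws. The median does not cover those pairs, for which a block deletion stays open, as do deletions within a gene. Mast cells among the Mcrs1ox cells are argued against as the source of Mcpt2 and Mcpt4, since 7 mast cell markers together had 0.131% of the 6849 counts of Mcpt2, and Cpa3 and Kit had 0. Another mast cell protease gene, Mcpt1, which is not among the 7, went with Mcpt2, at 6 counts in Control and 853 in Mcrs1ox. A candidate explanation that stays open is that the transduced cells grew from a subline unlike the control cells, apart from Mcrs1. The labels do not say how many Mcrs1ox lines were made. A subline therefore cannot be told apart from regulation by Mcrs1, which the design names and which stays open and untested.

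Genes on chromosome 18 were shifted down, with a median of -0.43 (interval -0.487 to -0.339) over 330 tested genes, of which 75.8% had a log2 fold change below 0. GC content and transcript length are argued against as the whole cause by a median of -0.395 after their trends were removed, and chance placing of single genes, with chromosome 18 chosen as the most extreme of 20 nuclear chromosomes, by a share of 1e-04 of 10000 shuffles in which any chromosome lay as far from 0, the smallest they can give. A candidate explanation is fewer copies of chromosome 18 in the Mcrs1ox cells, since each of 4 parts of the chromosome with about equal numbers of tested genes was lower, the highest at -0.316 and the others at -0.474, -0.407 and -0.479. Copy number itself was not analysed here, and regulation by Mcrs1 stays open and untested.

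For the MHC class I list, with a median of 0.45, more copies of the MHC region of chromosome 17 are argued against by the other 73 tested genes there, whose median was 0.127 (interval -0.0294 to 0.308). The list median also covers 10 tested members outside chromosome 17, whose own median was 0.307 and which copies of that region do not raise directly. GC content and length are argued against by a median of 0.562 after their trends were removed. Reads shared among heavy chain genes are argued against for H2-K1 and H2-D1 by the summed CPM of all 22 heavy chain genes, which rose from 758 ± 105 to 1454 ± 111 (log2 ratio 0.939). The other 13 members are not heavy chain genes, so such sharing does not bear on them. Their median of 0.353 (interval 0.287 to 0.832) shows only that the rise was not confined to heavy chain genes. The list's call is lost under an estimated correlation (adjusted p 0.32). An effect of Mcrs1 or of a subline stays open, as for the other genes.

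The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 6792 genes changed and 2164 by at least 2-fold, where the highest other gave 0 of each; in both, 1 of the 10 reached that value. For lists the real division gave 14 and the highest other 15, with 5 of the 10 at 14 or more. For the MHC class I list the real -log10 p was 2.26 and the highest other 2.84, with 4 of the 10 as high. Each other division still sets 2 libraries of a group against 1, so it holds part of the difference between the groups.

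On other chromosomes the median log2 fold change was 0.25 (interval 0.20 to 0.29) for chromosome 11 and -0.17 for chromosome 15, which holds Mcrs1. In absolute size both medians also exceeded that of any chromosome in the 10000 shuffles, and their cause was not tested. Of the genes named by the fixed rule, chromosome 11 holds Otop3, Lgals3bp, Krt19, Krt20, Srebf1, Aldoc and Stc2, which rose, and Mybbp1a, which fell. Chromosome 15 also holds Kansl2, which fell.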
